A study of Homo sapiens with 4 samples.

How the data were processed

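The series measured polyadenylated RNA in PC9 cells with the 10x Chromium Next GEM 3′ chemistry, as 1 parental library and 3 persister libraries labelled 1 day, 3 day and 1 week. Cell Ranger made the files, per the submitters' processing notes, which name GRCh38 (hg38); its version is not given in the sources used here. The deposited values of the parental library are raw UMI counts per gene and barcode in a filtered matrix, per the file headers. Barcode and gene lists were used of the persister libraries, whose count matrices were not used here. Groups were taken from the sample titles.

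Kept barcodes had at least 1000 genes and at most 20% mitochondrial UMIs, a filter fixed before the data were examined. It left out 1125 of 8997 barcodes, 749 with fewer genes and 450 with more mitochondrial UMIs, some with both. CPM were computed from summed counts of kept barcodes, with exact 95% Poisson intervals. Shares of barcodes have exact Clopper-Pearson 95% intervals, and a count of 0 was taken to allow up to 3 counts. Where a value is per barcode, each barcode was thinned to 2000 UMIs, and 730 kept barcodes with fewer were left out. With 1 library per group, all intervals cover counting error only.

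Genes with a mean of at least 0.05 thinned UMIs entered the list analyses, as log1p of thinned UMIs. For each of 29 lists fixed before the data were examined, the mean pairwise Pearson r was set beside 10000 random lists matched on mean expression, and a list above the 99th percentile was said to vary together. List scores were means of z-scored values. For the ends of a score, the 10% of barcodes with the highest and the lowest score of the other members were compared as a ratio of summed UMIs, with an interval from the binomial split of the counts, beside 1000 random lists (200 in the alternatives, except for the ATF4 programme). Random-list values given for the ends of a score are the 99th percentile of their median ratios. The ATF4 score was said to go together with or apart from a list when its r lay in the outermost 0.5% of random lists on either side. Fano factors were divided by a running median over 201 genes ordered by mean, for genes with a mean of at least 0.1. The window was shorter at the ends of the range, so the most abundant genes were set beside genes of lower mean. Genes outside all lists with a mean of at least 0.2 were correlated with the ATF4 score. No p-value was computed, since cells are not replicates.

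Named genes followed a rule fixed before the data were examined: members of the BCL2 family lists and the stress kinase list, EGFR, the 3 to 5 list members with the highest ratio at the ends of a score among those with a mean of at least 0.1 thinned UMIs, with members at most 1.2-fold apart beside them, the 15 highest and 10 lowest genes of the scan, the top 20 by Fano factor, the 10 most abundant genes and the top 5 members of each list by level. Deep values of list members and of the scan were picked by the same rule after they were seen. Values of some single genes are not reported here. Gene symbols follow the files; 570 of 570 gene identifiers looked up were found in GENCODE v29, which gave the GRCh38 coordinates.

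Doublets were sought with scrublet in scanpy 1.11.5, which marked 0 of 7142 barcodes and 0 of 3503 deep barcodes. A caller that marks none has not worked on data of this size, so doublets stayed in all values and settings without them could not be made. Clusters used 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and igraph 0.11.9.

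The list analyses were tested on simulated counts. Of 42 unchanged lists, 0 passed the 99th percentile for all kept barcodes (4914 genes) and 0 for deep barcodes (11060 genes), and both lists planted at each of 1.5-fold, 2-fold and 4-fold passed in each setting. The median ratio at the ends of the score came out at 1.12, 1.46 and 3.73 for these folds in kept barcodes and at 1.30, 1.85 and 4.03 in deep barcodes. In this simulation the ratios thus understated small folds. For 40 unchanged lists of 4 genes the ratio ranged from 0.85 to 1.40 in kept and from 0.71 to 1.25 in deep barcodes. This range is the noise of short lists in the simulation. The highest Fano factor relative to the running median was 2.47 in simulated kept barcodes, against 11.155 (MALAT1) in the library. In deep barcodes these values were 3.877 and 18.679 (MT-CO1). The simulated counts thus lacked the largest spreads of the library. How often unchanged lists pass where barcodes differ that much in content was therefore not tested.

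Settings chosen before the data were examined changed the thinning depth, the mitochondrial limit, the detection minimum, the width of the ends, the CPM denominator and the gene lists, or regressed out cell cycle scores or depth and quality. Settings on deep barcodes, on shallow kept barcodes and without the 10% of barcodes with the most UMIs, were added after seeing the data.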

Results

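PC9, a human lung adenocarcinoma line that carries an activating EGFR mutation, was profiled by droplet-based single-cell RNA sequencing. The series holds 1 library of parental cells and 3 libraries of persister cells, which survived the BH3 mimetics ABT737 (an inhibitor of the BCL2, BCL2L1 and BCL2L2 proteins) and S63845 (an inhibitor of MCL1), labelled 1 day, 3 day and 1 week; the event these times count from is not given in the sources used here. The lists of cell barcodes held 8997 barcodes for the parental library and 15898, 16743 and 13781 for the persister libraries at 1 day, 3 days and 1 week, each over 36601 genes. Pairs of libraries shared 40 to 70 barcodes, and the exact 95% Poisson intervals of the shared number per possible pair overlapped. Gene expression was analysed in the parental library, and the count matrices of the persister libraries were not used here, so parental and persister cells were not compared in expression. With 1 library per group there are no replicates: intervals given below cover counting error only, and correlations run across cells, which are not replicates.

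The parental library held 278834190 unique molecular identifiers (UMIs), and its barcodes fell into a shallow and a deep class. The 4956 barcodes under 10000 UMIs made up 55.1% of barcodes and 5.4% of UMIs, with a median of 2542.5 UMIs and 3.85% mitochondrial UMIs. The 3503 kept barcodes with at least 20000 UMIs, called deep below, held 90.9% of UMIs, with a median of 68297 UMIs, 7726 genes and 8.12% mitochondrial UMIs. The filter fixed before the data were examined kept 7872 barcodes, of which 7142 had the 2000 UMIs needed for analyses at equal depth, and many of these were shallow. Values per cell are therefore given for these 7142 barcodes and beside them for the deep barcodes thinned to 20000 UMIs, a setting chosen after seeing the data.

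**Figure D1:**
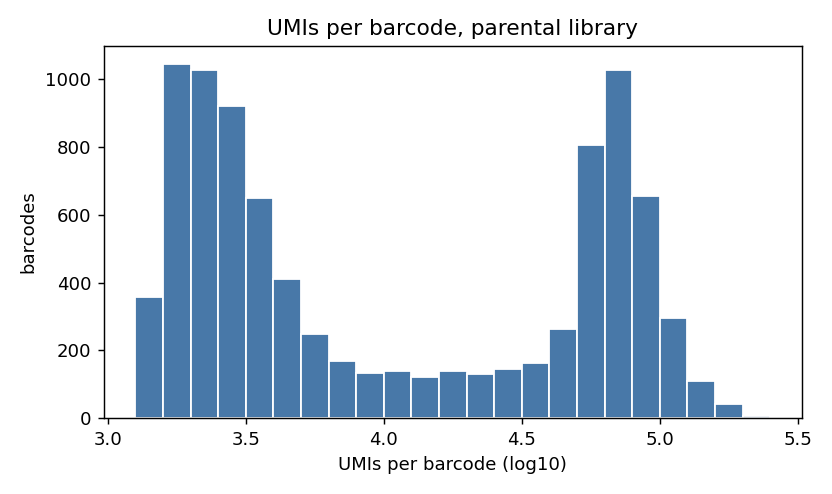
Number of parental barcodes by UMIs per barcode (log10 scale, bins of 0.1). The barcodes form a shallow and a deep class, with medians of 2542.5 UMIs below 10000 and 68297 UMIs in the deep barcodes. Shallow barcodes were most frequent near the low end of the filtered list (1045 in the bin from 3.2) and fell to 133 in the bin from 3.9. Their median therefore depends on that end and on the limit of 10000 UMIs.

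The most abundant transcripts of the parental cells were mitochondrial respiratory chain genes, ferritin and a heat shock protein. MT-CO2 stood at 17763 counts per 1000000 UMIs (CPM), MT-CO1 at 16669 and MT-CO3 at 13861, followed by the ferritin chains FTL (8571 CPM) and FTH1 (8245 CPM), the ribosomal protein gene RPS2 (8355 CPM) and the chaperone HSP90AA1 (7991 CPM). MT-ND4, MT-ATP6 and MT-CYB completed the top 10 at 7573, 7403 and 6063 CPM. Mitochondrial genes took 7.84% and ribosomal protein genes 18.68% of the UMIs in kept barcodes, in which 25632 genes had a UMI.

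Among the pro-survival targets of the 2 drugs, BCL2L1 and MCL1 were present at nearly equal levels and BCL2 was low. BCL2L1 (chromosome 20, 31664452 to 31723989, minus strand) stood at 53.9 CPM (95% interval 53 to 54.7) and MCL1 (chromosome 1, 150574551 to 150579738, minus strand) at 52.8 CPM (52.0 to 53.7). BCL2L2 reached 7.45 CPM, BCL2 2.88 CPM and BCL2L10 0.547 CPM, and BCL2A1 had 5 UMIs. At 20000 UMIs, 61.5% of deep barcodes had a BCL2L1 UMI, 63.3% an MCL1 UMI and 5.65% a BCL2 UMI. The share for BCL2 lay under the 7.14% reached by a fibroblast marker that this line should lack. That marker was the highest of the markers of absent cells apart from CD68 (37.9%), which is also made outside immune cells and was left aside after its value was seen. BBC3 (5.08%), EIF2AK3 (4.0%), BCL2L10, BMF and HRK did not pass this highest marker either. The median marker was far lower, at 0.029% for immune, 1.5% for endothelial and 0% for fibroblast and for erythroid and liver genes. The comparison therefore rests on 1 marker, and whether BCL2, BBC3 and EIF2AK3 lay above background in single cells was not settled.

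Of the death effectors and BH3-only genes, those for BAX, BAD and BID led. BAX, which permeabilizes the outer mitochondrial membrane, stood at 207 CPM (205 to 208) and its partner in that function, BAK1, at 14.1 CPM (13.6 to 14.5). BAD and BID reached 137 and 92.3 CPM, BOK 27.6, PMAIP1 (NOXA) 21.0, BIK 16.1 and BCL2L11 (BIM) 8.20 CPM. BBC3 (PUMA) stood at 2.29 CPM, BMF at 0.196 CPM and HRK at 0.148 CPM. Neither family passed as a list that varies together across deep barcodes. The mean pairwise r was 0.0049 for 4 pro-survival genes and 0.0017 for 9 BH3-only and effector genes, at the 63.1 and 49.6 percentiles of random lists. The simulations planted differences only in longer lists, so whether a true difference in lists this short would pass is not known.

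Of the genes upstream of the integrated stress response, which slows translation through phosphorylation of the factor encoded by EIF2S1, 3 of the 4 kinases were well represented. EIF2S1 stood at 325 CPM, EIF2AK1 (HRI) at 144, EIF2AK2 (PKR) at 123 and EIF2AK4 (GCN2) at 117 CPM, while EIF2AK3 (PERK) stood at 2.23 CPM (2.06 to 2.41). OMA1 and DELE1, which relay mitochondrial stress to EIF2AK1, stood at 10.8 and 13.1 CPM, and PPP1R15B at 20.2 CPM. Among 38 genes of the ATF4 programme, the amino acid transporters SLC3A2 (769 CPM), SLC7A5 (300.2 CPM) and SLC7A11 (248 CPM) were highest, followed by EPRS (230 CPM) and PHGDH (147 CPM). ATF4 itself (chromosome 22, 39519695 to 39522685, plus strand) stood at 109 CPM.

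The cells carried epithelial and basal keratins and few lung lineage transcripts. KRT7 stood at 3372 CPM, KRT18 at 2529, KRT19 at 1949 and KRT8 at 1352 CPM, and EPCAM at 556 CPM. Of 10 basal and squamous genes 7 reached 10 CPM, led by SFN (1024 CPM), S100A2 (326), KRT6A (153), KRT5 (139) and KRT17 (118 CPM). Of 15 lung lineage genes 1 did, FOXA1 at 22.7 CPM, and NKX2-1 had 2 UMIs. EGFR (chromosome 7, 55019021 to 55211628, plus strand) stood at 328 CPM and CCND1 at 407 CPM, and the detoxifying enzymes AKR1C3 of the NRF2 list and ALDH3A1 of the drug tolerance list stood at 1466 and 926 CPM. Markers of cells that should be absent summed to 26.9 CPM for immune cells, of which CD68 gave 25.8, and to 6.60 CPM for endothelial, 3.81 CPM for fibroblast and 0.059 CPM for erythroid and liver genes.

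To ask which programmes differ between untreated cells, the mean pairwise correlation of each fixed list was set beside random lists of like expression. In the 7142 barcodes 12 of 22 lists lay above the 99th percentile: the ATF4 programme, ER chaperones, MYC and ribosome biogenesis genes, EMT, epithelial, basal, EGFR and ERK output, immediate early and heat shock, NRF2, proteasome, S phase and G2M genes. The correlations were small, from 0.0058 for EGFR and ERK output to 0.0434 for G2M genes. The calls for EMT, epithelial, EGFR and ERK output, immediate early and proteasome genes were lost at 1000 UMIs, and those for EMT and for EGFR and ERK output also with depth and quality regressed out. In the shallow kept barcodes alone 7 lists passed, and the ATF4 programme was not among them (98.54 percentile), although it passed from 2000 to under 3000 UMIs (99.82) and from 3000 to under 5000 UMIs (99.99) and not from 5000 to under 10000 UMIs (86.37) or from 10000 to under 20000 UMIs (49.02). In deep barcodes at 20000 UMIs all 12 again lay above the 99th percentile and 18 of 25 lists did in total. YAP, cholesterol, NF-kB, hypoxia and p53 target genes were added, as were interferon genes, which could not be tested at 2000 UMIs. In the deep barcodes the G2M list reached 0.276, the basal list 0.167, S phase genes 0.115, NRF2 genes 0.0869 and the ATF4 programme 0.0395.

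**Figure D2:**
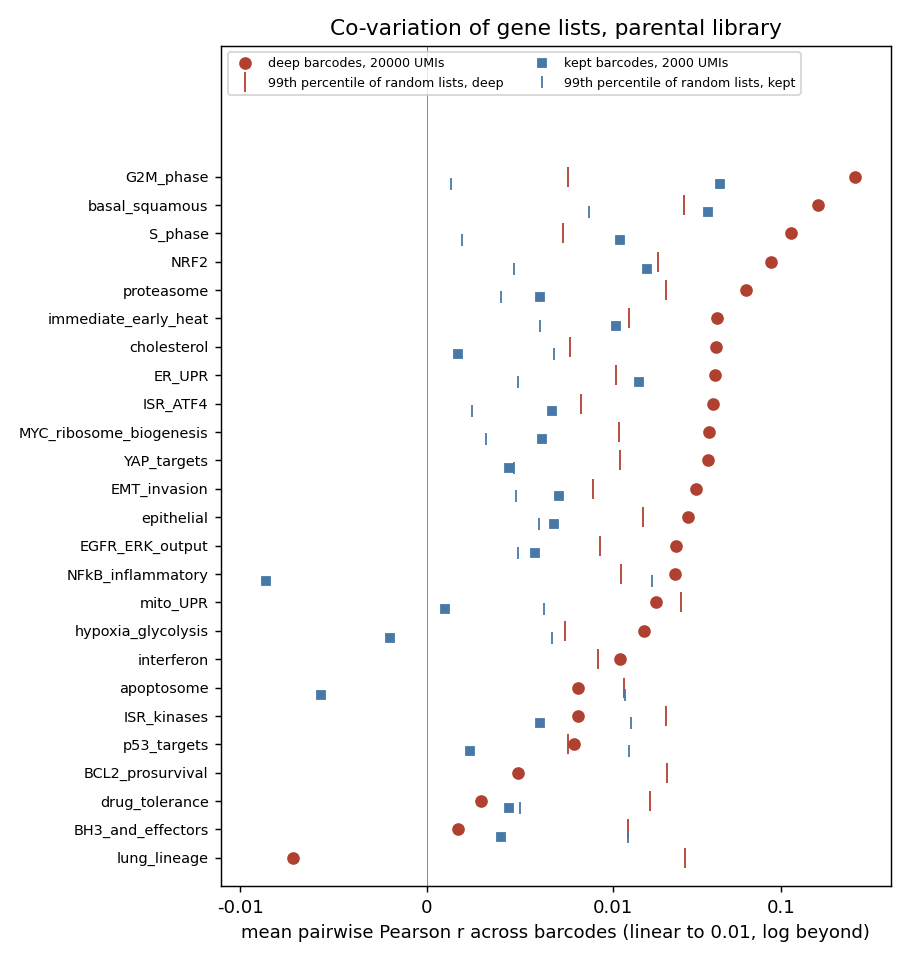
Mean pairwise Pearson r of the detected members of each fixed gene list, across kept parental barcodes at 2000 UMIs (squares) and deep barcodes at 20000 UMIs (circles), on an axis that is linear to 0.01 and logarithmic beyond; vertical marks give the 99th percentile of 10000 random lists. The G2M list was highest in both settings, at 0.0434 and 0.276.

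Along the ATF4 score, CTH, STC2, TRIB3, PSAT1 and GARS differed most in deep barcodes among members with a mean of at least 0.1 UMIs there. At 2000 UMIs CTH and STC2 lay under the detection minimum, and TRIB3, with a mean of 0.055 UMIs, differed 1.162-fold (0.731 to 1.855). Between the 10% of barcodes with the highest and the 10% with the lowest score of the other members, PSAT1 (serine synthesis) differed 1.46-fold (1.19 to 1.80) and GARS (glycyl-tRNA synthetase) 1.29-fold (1.06 to 1.56) at 2000 UMIs, while SLC7A5 differed 1.06-fold and PSPH 1.05-fold. The median over 21 members was 1.10, under the 1.13 that marks the 99th percentile of random lists, so the ends were not called in this setting. At 1000 UMIs (1.21) and with 20% of barcodes at each end (1.12) the median passed that percentile. In deep barcodes at 20000 UMIs the median over 28 members was 1.60 against 1.16 at the 99th percentile of random lists, and 25 members had an interval above 1. CTH (cysteine synthesis) then differed 4.04-fold (2.59 to 6.54), STC2 2.92-fold, TRIB3 2.86-fold, PSAT1 2.65-fold (2.42 to 2.90), GARS 2.19-fold and ATF4 2.10-fold (1.90 to 2.32). The members named at 20000 UMIs here and below, and any others named there, were chosen by the same rule after their values were seen.

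**Figure D3:**
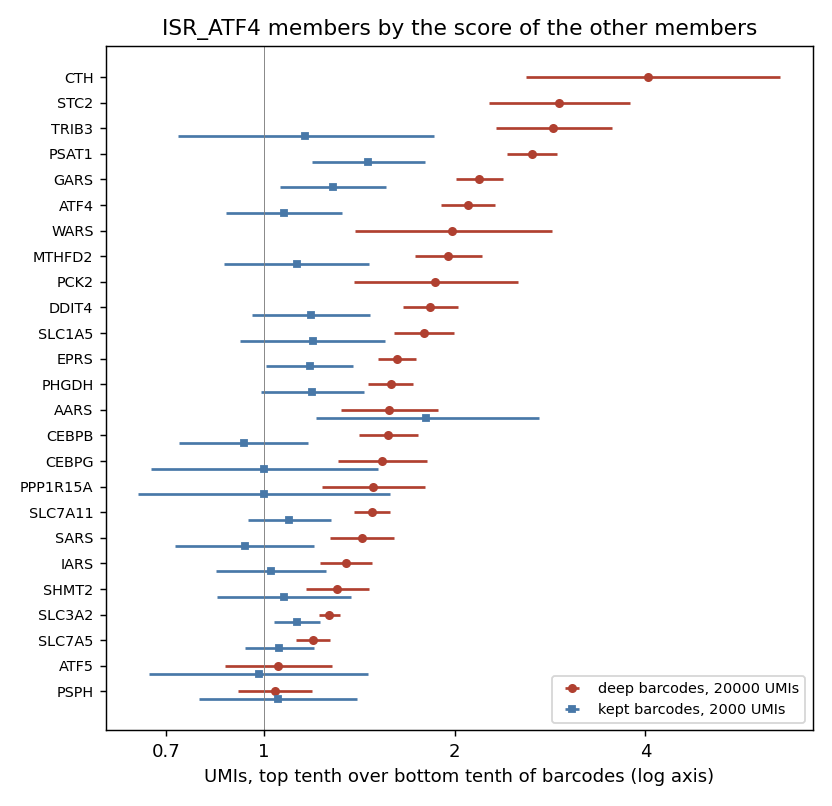
Ratio of UMIs between the top and the bottom 10% of parental barcodes by the score of the other ATF4 programme members, per gene, on a log axis; squares are kept barcodes at 2000 UMIs, circles deep barcodes at 20000 UMIs, and bars exact 95% intervals of counting error. CTH lay highest among the deep barcodes at 4.04.

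Basal keratins and aldo-keto reductases differed along their own scores. KRT6A differed 2.25-fold (1.84 to 2.77), KRT17 2.12-fold and KRT5 1.99-fold between the ends of the basal score at 2000 UMIs, and in deep barcodes TP63, the basal master regulator, differed 6.30-fold (4.35 to 9.40), KRT6A 4.71-fold and KRT5 4.20-fold. The median over basal members was 1.96 at 2000 UMIs and 3.93 in deep barcodes, against 1.14 and 1.16 for random lists. Along the NRF2 score the aldo-keto reductases AKR1B10 and AKR1C1 differed 1.84-fold (1.66 to 2.04) and 1.43-fold at 2000 UMIs, and 3.79-fold (3.58 to 4.0) and 2.34-fold in deep barcodes, where GCLC differed 2.10-fold, whereas TXNRD1 differed 1.04-fold at 2000 UMIs; the NRF2 medians were 1.21 and 1.62. The AKR1 genes and the keratins have close copies whose reads the counting could split, so values of single members are uncertain.

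Chaperones of the endoplasmic reticulum differed as a group, with CANX at 1.5-fold (1.29 to 1.74), DNAJB11 at 1.45-fold, SDF2L1 at 1.45-fold and HSPA5 at 1.4-fold, and a median of 1.32 over 11 members against 1.13 for random lists. In deep barcodes at 2000 UMIs the median was 1.207 against 1.157 at the 99th percentile of random lists, but CANX differed only 1.07-fold (0.857 to 1.331). At 20000 UMIs in deep barcodes HSPA5 differed 2.13-fold (2.02 to 2.26), HERPUD1 1.96-fold and XBP1 1.88-fold, and the median was 1.46. Along the list of EGFR and ERK output, the feedback genes DUSP5, DUSP6 and SPRY2 differed 2.19-fold, 2.05-fold and 1.90-fold in deep barcodes, where the median was 1.5 against 1.17 for random lists. At 2000 UMIs its median was 1.22 against 1.14, a call lost at 1000 UMIs (1.04), with 20% of barcodes at each end (1.07) and in deep barcodes at 2000 UMIs (1.17). EMT genes had a median of 1.18 at 2000 UMIs, under the 1.21 of random lists. With 20% of barcodes at each end the EMT median was 1.16, narrowly above the 1.15 of random lists. It lay under random lists at 1000 UMIs (1.095 against 1.281) and in deep barcodes at 2000 UMIs (1.116 against 1.372). In deep barcodes at 20000 UMIs it was 1.69, and VIM differed 3.32-fold. Cholesterol synthesis genes did not vary together at 2000 UMIs but had a median of 1.91 in deep barcodes, led by INSIG1 (3.96-fold), MSMO1 (3.25-fold) and HMGCS1 (2.88-fold).

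The drug tolerance genes, among them AXL and CD44, did not pass as a list that varies together. Its mean pairwise r lay at the 98.0 percentile in the 7142 barcodes and at the 51.7 percentile in deep barcodes, where CD24 differed 1.48-fold (1.35 to 1.62) between the ends of the score, AXL 0.986-fold, CD44 0.960-fold and ALDH3A1 0.877-fold (0.848 to 0.908), with 3 of 11 intervals above 1 and 2 below. Its median ratio was 1.16 at 2000 UMIs, above the 1.12 of random lists, but did not pass random lists in any other setting and was 0.989 in deep barcodes. MCL1 differed 0.992-fold (0.860 to 1.15) and BCL2L1 0.978-fold (0.843 to 1.14) between the ends of the pro-survival score in deep barcodes.

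G2M genes set cells apart most. Between the ends of the G2M score the mitotic kinase AURKA differed 10.6-fold (7.44 to 15.5), TOP2A 9.89-fold, CENPA 9.74-fold and CENPE 9.27-fold at 2000 UMIs, against 1.33-fold for CBX5, with a median of 4.27 over 49 members. In deep barcodes the median over 52 members was 7.93; GAS2L3, with few UMIs, differed 84.0-fold (28.4 to 410.1), AURKA 31.1-fold (24.1 to 40.9) and CENPE 30.4-fold. Along the S phase score ATAD2 differed 3.19-fold, CLSPN 2.79-fold and CDCA7 2.33-fold, with a median of 1.58. Phase calls assigned 75.5% (74.5 to 76.5) of the 7142 barcodes to G2M, 14.9% to S and 9.61% to G1, but the G2M share was 34.2% with a random 50% of each list, so these shares depend on the gene lists and carry no reading of cycling.

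The ATF4 score rose with the G2M score. Across the 7142 barcodes r was 0.0503, at the 99.97 percentile of random lists, and with EGFR and ERK output it was 0.0415, at the 99.63 percentile, while no list went the opposite way. In deep barcodes at 20000 UMIs r with the G2M list was 0.159, beyond all 10000 random lists, and r with S phase genes was −0.0897, below all of them, and EGFR and ERK output was at the 97.8 percentile and no longer called. Across the shallow kept barcodes r with the G2M list was 0.0083, at the 66.8 percentile, and the ATF4 score went with ER chaperones (r = 0.0489) and NRF2 genes (0.0409), both at the 99.74 percentile, and apart from apoptosome genes (−0.0602). The G2M relation was lost at 2000 UMIs once depth, mitochondrial and ribosomal share were regressed out, at the 97.7 percentile, and its percentile was 0 without thinning. In deep barcodes it was no longer called with the MALAT1 share regressed out (r = 0.0977, 98.84 percentile) and lay at the threshold without SLC7A11, DDIT4 and ATF4 (r = 0.0978). The EGFR and ERK relation was also lost at 1000 UMIs (97.86), at no more than 10% mitochondrial UMIs (98.58) and with depth and quality regressed out (98.02). Further losses came at a detection minimum of 0.2 (97.06) and without thinning, where the ATF4 score went with no list.

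Beyond the fixed lists, EIF2S2, YARS, MALAT1 and TARS had the highest r with the ATF4 score in deep barcodes. Among the 15 highest of 7430 genes were the initiation factors EIF2S2 (r = 0.206) and EIF1 (0.176), the tRNA synthetases YARS (0.204), TARS (0.198) and CARS (0.150) and the tRNA exporter XPOT (0.143), with MALAT1 at 0.203 and the mitotic gene ASPM at 0.148. SLIRP, which stabilizes mitochondrial mRNA, was lowest at −0.180, followed by LY6D (−0.165), the glutathione peroxidase GPX2 (−0.162) and, among others, the ribosomal protein genes RPS24 (−0.160), RPL32 (−0.151) and RPL28 (−0.135). At 2000 UMIs the highest of 1484 genes were HMGN2 (0.054), RTN4 (0.041) and H1FX (0.040) and the lowest was SLIRP (−0.057). The scan at 2000 UMIs repeated poorly, with r = 0.209 across genes between random parts of the cells against 0.545 in deep barcodes, and 5 of 25 genes were shared between the depths; genes are not independent replicates.

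MALAT1, a nuclear noncoding RNA, and mitochondrial genes had the highest Fano factors relative to the running median. That ratio may favour abundant genes, which were set beside genes of lower mean: at 2000 UMIs MT-CO2 had a mean of 27.2 UMIs and UBE2C 0.569. The ranking therefore does not show which genes varied most in proportion to their level. At 2000 UMIs the Fano factor of MALAT1 was 11.2 times the running median, followed by MT-CO2 at 8.67, MT-CO1 at 8.64 and MT-CO3 at 6.74. Outside the mitochondrial genome HSP90AA1 stood at 2.50, the nuclear RNA NEAT1 at 2.41, the histone gene HIST1H4C at 1.84, FTH1 at 1.74, S100A4 at 1.45, the mitotic gene UBE2C at 1.45 and the keratin KRT13 at 1.4. In deep barcodes at 20000 UMIs MT-CO1 (18.7), MT-CO2 (15.2) and MT-CO3 (14.4) stood above MALAT1 (14.0), and 15 of the top 20 genes were shared. The Fano factor of MALAT1 at 2000 UMIs was 27.1 in shallow kept and 3.98 in deep barcodes. Leiden clustering split the 7142 barcodes into 3713, 3381 and 48, with median UMIs of 3501, 60784 and 2564. The clusters differed in depth and also in content. Their median mitochondrial shares were 3.56%, 8.36% and 4.41%, and 7 of the top 10 genes of the largest were in the G2M list. They were left unnamed.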

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

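MALAT1, a nuclear noncoding RNA, was high in barcodes that the filter left out of the report. No test in this part was chosen after its result was seen, because none was run. The 357 parental barcodes left out for over 20% mitochondrial UMIs, with at least 5000 UMIs each, had 12385 MALAT1 CPM (95% interval 12303 to 12468) beside 4492 CPM (4484 to 4500) in deep barcodes. Without mitochondrial UMIs the values were 19737 and 4885 CPM. The result stands here because it is a signal in data outside the main measurement, and no biological explanation was tested.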

How the results depend on the processing

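In this part, the settings on deep barcodes, on shallow kept barcodes and without the 10% of barcodes with the most UMIs were chosen after seeing the data. Labels for the ends of scores were set again after a first set was seen, so that each setting is judged by its own random lists. Of the results on single genes and lists, 530 stayed the same, 127 moved, 42 were stronger, 42 weaker and 3 reversed. Of the others, which are the headline results, 32 stayed the same, fewer than the 36 that moved, while 4 were stronger and 2 weaker. The cause was not tested for any change below, except where stated.

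The number of lists varying together, 12, was 7 at 1000 UMIs, 3 without thinning and 7 in shallow kept barcodes, and 9 to 18 elsewhere. The ATF4 programme no longer varied together without thinning (94.67 percentile) or in shallow kept barcodes (98.54). By depth, it passed from 2000 to under 3000 UMIs (99.82) and from 3000 to under 5000 UMIs (99.99), but not from 5000 to under 10000 UMIs (86.37) or from 10000 to under 20000 UMIs (49.02), where barcodes were fewest. The median ratio at the ends of its score, 1.10, was not above the 99th percentile of random lists. It was above that percentile at 1.21 with 1000 UMIs, 1.12 with 20% of barcodes at each end, 1.30 in deep barcodes at 2000 UMIs and 1.60 at 20000 UMIs. The median ratio of the drug tolerance list, 1.16, was 1.01 at 1000 UMIs, 1.07 with 20% at each end, 0.961 in deep barcodes at 2000 UMIs and 0.989 at 20000 UMIs. None of these was above the 99th percentile of random lists. The values in deep barcodes are counted as reversed for lying under 1, but no member interval excluded 1 at 2000 UMIs and members went both ways at 20000 UMIs. The ATF4 score went with 2 lists and apart from 0. It went with 1 at 1000 UMIs, 0 without thinning, 1 at no more than 10% mitochondrial UMIs, 1 with cell cycle scores regressed out (which takes the G2M and S phase lists out of the test), 0 with depth and quality regressed out and 1 at a detection minimum of 0.2. In deep barcodes it went with 1 at 2000 UMIs, 1 at 20000 UMIs, 0 there with cell cycle scores and 1 there with depth and quality regressed out. It went apart from 6 lists without thinning, where the G2M percentile reversed to 0, and in deep barcodes from 1 at 2000 UMIs, 1 at 20000 UMIs and 1 there with depth and quality regressed out, and in shallow kept barcodes from 1, while it went with 2 other lists.

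The G1, S and G2M shares, 9.6%, 14.9% and 75.5%, were 26.7%, 18.2% and 55.2% at 1000 UMIs, 32.7%, 33.0% and 34.2% with 50% of each gene list, 22.4%, 21.1% and 56.5% in deep barcodes at 2000 UMIs, 10.4%, 17.6% and 72.1% at 20000 UMIs, and 8.0%, 10.7% and 81.3% in shallow kept barcodes. Of the 25 scan genes 4 were shared at 1000 UMIs, where fewer genes were tested, and 5 in deep barcodes at 20000 UMIs. The 3 clusters became 2 at Leiden resolution 0.3 and 6 at resolution 1.0. Alternatives without doublets gave no values, since none were marked. No paired analysis was possible because each group has 1 library, and no replicate could be left out. At 2000 UMIs most list members have few UMIs per barcode, which limits every value per barcode.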

Other observations

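In this part, the tests of free RNA at 3 depths, of lost cytoplasm, and of depth and quality were chosen after the results were seen, as were all settings on deep barcodes, the spread of random draws asked for around a threshold, and the comparison with a trimmed mean for MALAT1; the other tests were chosen before. EMT genes stood higher in the 357 barcodes with over 20% mitochondrial UMIs and at least 5000 UMIs than in deep barcodes, with mitochondrial and ribosomal protein genes left out of both totals. The median log2 difference over 16 EMT genes was 0.76, above all 10000 random lists, and 15 members were above 0, in barcodes where MALAT1 without mitochondrial UMIs stood at 19737 CPM against 4885. FN1, which encodes fibronectin, stood 3.13-fold higher, the integrin gene ITGAV 2.09-fold and THBS1 2.02-fold. The shift was not confined to them: YAP targets had a median of 0.50 (99.58 percentile), drug tolerance genes 0.25 (99.63), epithelial genes 0.24 (99.72, with CDH1 at 2.24-fold and KRT18 at 0.809-fold), G2M genes 0.11 (99.80) and NRF2 genes −0.01 beside −0.27 for random lists (99.46), and the ATF4 programme 0.02 (72.77). EGFR stood 1.58-fold and MCL1 1.47-fold higher. These genes were picked after their values were seen.

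Shallow kept barcodes carried slightly more basal, NRF2 and G2M transcripts than deep barcodes, and less MALAT1 (2453 against 4492 CPM) and mitochondrial RNA (4.17% against 8.05% of UMIs). The median log2 difference was 0.27 over 7 basal genes, at the 99.97 percentile of random lists, 0.10 over 16 NRF2 genes (99.63) and 0.11 over 52 G2M genes (99.99). KRT5 stood 1.27-fold and AKR1B10 1.18-fold higher, EGFR 1.01-fold and MCL1 0.907-fold. These genes were also picked after their values were seen.

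The 4956 barcodes under 10000 UMIs were weighed as droplets without intact cells. For the 3377 kept ones with at least 2000 UMIs, free RNA as the content of every barcode does not go with the G2M list varying together: the percentile was 100 in the 1722 barcodes from 2000 to under 3000 UMIs (mean r 0.0192), 100 in the 1185 from 3000 to under 5000 (0.0283) and 100 in the 470 from 5000 to under 10000 (0.0441), so part of them, and the barcodes not tested, may still be free RNA. If all were cells that lost their cytoplasm, MALAT1 would be high, but over all 4956 it stood at 2627 CPM (2601 to 2653) against 4492 in deep barcodes, which leaves open that some of them are such cells. Pieces without a nucleus fit a share of them, but not securely. Of 3377 kept ones 8.11% had no MALAT1 UMI at 2000 UMIs against 0.63% under a Poisson draw. That excess of 7.48 percentage points (6.58 to 8.46) passed the minimum asked for beforehand. With a trimmed mean the lower limit fell to 4.62 points, under that minimum, which leaves the question open. Deep barcodes also exceeded the draw, at 1.26% against 0.02%, and spread in MALAT1 (Fano factor 27.1) raises the share too. A second barcode in a deep droplet, 1 base apart, cannot be told apart from chance, because 0% had such a neighbour, but all 55095 distinct barcodes of the 4 libraries held 0 such pairs where random sequences of 16 bases would give 17.0, so the barcode set fixes the outcome and the bound set beforehand was wrong, and no biological explanation was tested.

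The ATF4 score rising with the G2M score in deep barcodes (r = 0.159) was weighed against barcode quality and list make-up. Depth and quality do not account for all of it, since r was 0.109 with depth, mitochondrial and ribosomal share regressed out and 0 of 10000 random lists were as high, although in all kept barcodes the same correction lowered r from 0.0503 to 0.0195 and ended the call. More nuclear RNA per barcode may account for it: with the MALAT1 share regressed out r fell to 0.0977 and 116 random lists were as high, which ended the call. The random lists were scored with the same correction, so their values may have moved as well. Whether a few members carry it cannot be told apart from chance: without SLC7A11, DDIT4 and ATF4 r was 0.0978 and 50 random lists were as high, exactly at the threshold, with 19 of 25 members still positive, and leaving out the highest members biases r down. No biological explanation was tested, and 1 library gives no replicate.

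The NRF2 and basal lists varying together in deep barcodes were weighed against reads shared between close gene copies. Leaving out the pairs within the AKR1 family, the other 130 NRF2 pairs had a mean r of 0.0745 beside 0.0175 for the 99th percentile of random lists, at the 100 percentile. Leaving out pairs within keratins of 1 type, the other 19 basal pairs had a mean r of 0.159 beside 0.0279, also at the 100 percentile. Shared reads as the whole cause therefore do not account for either, while copies may still raise single values, and no biological explanation was tested.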
